A study of Rattus norvegicus with 18 samples.

How the data were processed

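The table holds linear intensity per probe set, produced by the authors with the software GCOS 1.4 on the Affymetrix Rat Genome 230 2.0 array and scaled to a common 2% trimmed mean. The algorithm that made the signals was not stated, and the raw image files were not used here. The 18 columns were matched to the 18 arrays through the sample descriptions. The 11 comparisons, their test and threshold, the 26 gene lists, the rule for naming genes and most alternatives were written down before the data were examined. Tests and alternatives added later are named as such where they are given.

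Of 31099 probe sets, 57 array controls were left out. A probe set was kept where its signal was above 40.8, the 40th percentile of all values, in at least 3 of the 18 arrays, which left 21675. Signals were analysed as log2(signal + 5.5), where 5.5 is the 10th percentile of all values. No further scaling was applied because the highest array median was 1.424 times the lowest, under the limit of 1.5. Because total and polysomal arrays were scaled alike, a polysomal over total ratio is relative.

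Each probe set was fitted with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with a variance trend), with 6 group means and 12 residual degrees of freedom. All p-values of single genes are moderated t tests of limma. They were adjusted with the Benjamini-Hochberg method over all probe sets kept, and the threshold was an adjusted p under 0.05. The mean ratio over the 3 stages averages the polysomal minus total contrasts of the stages, and a ratio change is the difference of these contrasts between stages. SE is that of limma, and SD is that of 3 arrays. Gene lists were tested with camera of limma with a preset correlation between genes of 0.01, adjusted over 26 lists, and again with an estimated correlation. Members were also adjusted over the list alone. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

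The total and polysomal arrays with the same number at the same stage came from the same lysate per the design. Their deviations from the group means correlated in 9 of 9 cases, with r from 0.186 to 0.488, so a second fit took the lysate as a block with 6 residual degrees of freedom. Across stages equal numbers were taken as pairs where all 3 deviations correlated above 0.1. Of the stage comparisons this held for polysomal RNA at FD19 and FD22 (0.226 to 0.498), where the labels name no shared litter, batch or day and the pairing rests on the data alone. The third principal component, with 10.19% of the variance, placed the 6 arrays numbered 1 at 14.36 to 37.54 and the other 12 at -37.86 to 1.09. The array numbered 1 also had the lowest median signal in 6 of 6 groups. A processing batch was not recorded, and comparisons without these arrays were added after seeing the data.

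Of the probe sets other than controls, 20826 were annotated to 1 gene, 436 to several and 9780 to none. Entrez identifiers matched 20764 of them to the gene table of the present rat assembly, and 0 symbols changed. Each of 11590 genes was represented by its kept probe set with the highest mean over the 18 arrays, and other probe sets of a named gene were checked for opposite calls. The 26 lists covered cell types, processes of the perinatal lung and classes of translationally regulated mRNA. Ribosomal protein, initiation factor and respiratory chain genes were taken by symbol and the others from general knowledge. Each list needed at least 5 measured genes, and 26 were testable.

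Genes were named by a fixed rule. For the total RNA comparisons, the mean ratio and the ratio changes it took the 6 highest and 6 lowest called genes without overlap between groups, or up to 4 with the smallest p where none passed. It also took up to 4 called members of each list, and always Sftpa1, Sftpb, Sftpc, Sftpd, Scnn1a, Scnn1b, Scnn1g, Vegfa and Igf2. The text gives a selection of the list members, preferring genes whose call did not depend on 1 lysate.

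The fit was tested on simulated data, drawn as normal noise with the mean and residual SD of each probe set and without the sharing of lysates, with known changes in 200 probe sets. For total RNA at FD22 against FD19 it recovered 22.4% of 1.5-fold, 58.2% of 2-fold and 95.5% of 4-fold changes, and 8.6% of its calls were false. For the mean ratio the shares were 65.7%, 89.6% and 100%, with 6.1% false. For the ratio change between FD22 and P1 they were 3%, 29.9% and 75.8%, with 1.4% false. The Benjamini-Hochberg cutoff depends on how many probe sets change. The real data gave 3520 calls for total RNA at FD22 against FD19 and 10057 for the mean ratio. For these 2 comparisons the simulated shares recovered may therefore be too low.

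Alternatives written down at the start were the 1st (0.9) and 30th (26.3) percentile as the constant added, no filter (31042 probe sets), a filter at the 60th percentile (96.4, with 14784 probe sets), quantile normalization, median centring, no variance trend, only the arrays compared, 1 probe set per gene, a block, and each lysate left out. The list medians were compared with 10000 random lists matched on mean expression, each member drawn from its 200 nearest genes. Group labels were exchanged in all 10 ways of splitting 6 arrays or lysates, and in 100 random ways for the mean ratio. The 3'/5' signal ratios of beta-actin and Gapdh were correlated with the list medians after subtracting stage means, against all 216 orders within stages, and used as a covariate in a linear model of stage, both after the results were seen. The correlation of total and polysomal stage changes was compared with 100 draws without stage effects.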

Results

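Rat lung was compared at 3 stages around birth, in whole-lung RNA and in RNA recovered from large polysomes, the fraction in which many ribosomes translate one mRNA at a time. Lungs of Wistar fetuses were taken on fetal day 19 (FD19, canalicular lung) and fetal day 22 (FD22, shortly before birth), and lungs of newborns 5 h after birth (P1). Each stage held 3 litters and therefore 3 lysates, and each of the 9 lysates gave 1 array of total RNA and 1 array of polysomal RNA (more than 7 ribosomes per mRNA). The 18 arrays thus formed 6 groups of 3. All arrays had been scaled to nearly the same 2% trimmed mean signal, between 149.6 and 150.0, and their median signals lay between 51.6 and 73.5. Of 31099 probe sets, 21675 were bright enough to be tested, and they represented 11590 named genes. Changes are differences of log2 signal with the standard error (SE) of limma, n = 3 arrays per group, and the p-values were adjusted for all probe sets tested. The number of arrays limits the precision.

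The comparison of FD22 with FD19 in total RNA asked how steady-state RNA changed as the canalicular lung became the lung that is ready for birth. Genes of the gas-exchange epithelium rose and genes of the cell cycle fell. Ager, a receptor of alveolar type I cells, rose by 3.47 ± 0.25 (adjusted p = 1.29e-07), and the surfactant protein gene Sftpa1 rose by 2.15 ± 0.12 (adjusted p = 9.26e-09), from a signal of 818 ± 112 (SD, n = 3) to 3632 ± 216. All 47 measured cell cycle genes fell, with a median log2 change of -1.24. Of the 21675 probe sets, 1824 were higher and 1696 lower at FD22, and 1123 of these 3520 differed by more than 2-fold. The 3 arrays of each stage did not overlap for 3443 of the 3520, and for 33.28% of all probe sets, where chance gives 10%.

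The largest rises were those of Atp6v1c2 (5.67 ± 0.57), a proton pump subunit, and Scd (5.22 ± 0.63), the desaturase that makes monounsaturated fatty acids. Fetub rose by 4.69 ± 0.47, the antimicrobial peptide gene Defb4 by 4.60 ± 0.80, the chitinase gene Chia by 4.54 ± 0.54 and the secreted phospholipase gene Pla2g1b by 4.31 ± 0.36. The highest adjusted p among these 6 genes was 0.000496, for Defb4. The signals of Atp6v1c2 (6.1 ± 4.0) and Scd (11.8 ± 3.1) at FD19 were close to the constant added before taking logs, and their changes ran from 4.20 to 6.48 and from 4.12 to 5.67 over the settings tried. The deepest falls were those of the embryonic claudin gene Cldn6 (-4.07 ± 0.38), the embryonic globin gene Hbz (-3.52 ± 0.42) and the cartilage collagen gene Col2a1 (-3.10 ± 0.41). Uchl1, a neuronal hydrolase, fell by 2.98 ± 0.41, the mitosis gene Gtse1 by 2.69 ± 0.44 and the cartilage gene Mia by 2.62 ± 0.18, and the highest adjusted p among the 6 was 0.000308. Low signals also bore on Cldn6 (6.6 ± 1.5) and Hbz (5.4 ± 4.8) at FD22.

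Alveolar type II cells make surfactant, and 14 of the 19 genes measured for them rose while 2 fell (15 and 2 adjusted over the list alone; median 0.97, camera adjusted p = 4.83e-11). Beside Sftpa1, the surfactant genes Sftpb (1.92 ± 0.19) and Sftpd (1.66 ± 0.19) and the surfactant protease gene Napsa (3.06 ± 0.31) rose. Sftpc, whose signal of 5656 ± 360 at FD19 was already among the brightest, stood at 0.28 ± 0.21 (adjusted p = 0.417) and passed the test only after quantile normalization (adjusted p = 0.00119). All 12 alveolar type I genes rose, as they did over the list alone (median 1.36, adjusted p = 5.1e-15). Akap5 (2.65 ± 0.35), the water channel gene Aqp5 (2.28 ± 0.47) and Hopx (2.06 ± 0.21) were the steepest after Ager. Of 11 airway club and ciliated cell genes 9 rose (11 adjusted over the list alone; median 1.19, adjusted p = 7.18e-09). The secretoglobin genes Scgb3a1 and Scgb1a1 rose by 2.81 ± 0.34 and 1.21 ± 0.15. Vegfa, the endothelial growth factor gene also counted among the type I genes, rose by 0.57 ± 0.18 (adjusted p = 0.0318), a call that ended without any 1 lysate except FD22 replicate 2. Its adjusted p was 0.0662, 0.109 and 0.0819 without FD19 replicates 1, 2 and 3, and 0.138 and 0.115 without FD22 replicates 1 and 3.

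The lung must turn from secreting liquid to absorbing it at birth. Of its genes of lung liquid and ion transport, 11 of 23 rose while 0 fell (11 and 0 adjusted over the list alone; median 0.61, camera adjusted p = 9e-06, but adjusted p = 0.0563 with an estimated correlation). All subunit genes of the epithelial sodium channel rose before birth: Scnn1a by 2.66 ± 0.26 (adjusted p = 2.43e-06), Scnn1g by 1.75 ± 0.21 (1.37e-05) and Scnn1b by 0.84 ± 0.19 (0.00412). Sgk1, a kinase that activates this channel, rose by 1.85 ± 0.17. Of 24 genes of the glucocorticoid response and clock, 13 rose and 1 fell (16 and 1 adjusted over the list alone; adjusted p = 1.94e-07, but adjusted p = 0.103 with an estimated correlation). The hormone-induced transcription factor genes Cebpd and Klf9 rose by 1.54 ± 0.33 and 1.31 ± 0.30. Immediate early genes rose in 8 of 33 cases (10 adjusted over the list alone; adjusted p = 0.00218, but adjusted p = 0.154 with an estimated correlation). Dusp1, a phosphatase of stress kinases, rose by 1.34 ± 0.24 and Klf2 by 1.30 ± 0.16.

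The cell cycle list, 47 genes lower over all genes and 47 adjusted over the list alone, passed camera with adjusted p = 8.07e-33. Its deepest falls were those of the mitotic kinase gene Ttk (-2.14 ± 0.37), the cyclin gene Ccna2 (-2.05 ± 0.29), Ect2 (-2.01 ± 0.19) and Bub1b (-1.81 ± 0.23). Igf2, the main fetal growth factor gene, fell by 1.03 ± 0.17 (adjusted p = 0.000284). In the fetal growth and imprinted list 7 of 21 genes fell while 1 rose (8 and 1 adjusted over the list alone; adjusted p = 0.000979). Translation initiation factor genes fell in 15 of 45 cases (21 lower and 1 higher adjusted over the list alone; median -0.31, adjusted p = 3.25e-05), with the helicase gene Eif4a1 at -0.70 ± 0.15. Of 79 oxidative phosphorylation genes 21 fell and 2 rose (30 and 2 adjusted over the list alone; median -0.33, adjusted p = 3.66e-07, but adjusted p = 0.314 with an estimated correlation). After quantile normalization 13 fell. Atp5f1a, a subunit of ATP synthase, stood at -0.78 ± 0.14, while the muscle form Cox7a1 rose by 1.14 ± 0.20. Ribosomal protein genes fell in 6 of 44 cases (3 adjusted over the list alone; median -0.21, adjusted p = 4.87e-05, but adjusted p = 0.399 with an estimated correlation). After quantile normalization 1 fell (list adjusted p = 0.0819). Other mRNAs with a 5-prime TOP motif, the element that couples translation to nutrient signals, fell in 6 of 13 cases (6 adjusted over the list alone; adjusted p = 0.0141, but adjusted p = 0.314 with an estimated correlation, and 0.332 after quantile normalization, with 2 lower). The elongation factor gene Eef1b2 fell by 0.53 ± 0.11.

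Endothelial genes rose in 19 of 27 cases (20 adjusted over the list alone; median 0.69, camera adjusted p = 1.58e-11). Ace, the converting enzyme of lung capillaries, rose by 2.06 ± 0.20 and Thbd by 1.61 ± 0.17. Leukocyte genes rose in 20 of 25 cases (22 adjusted over the list alone; median 1.09, adjusted p = 1.1e-14), with the macrophage lysozyme gene Lyz2 at 1.89 ± 0.26 and Cd74 at 1.85 ± 0.15. Erythroid genes fell in 5 of 17 cases and rose in 1 (6 and 1 adjusted over the list alone; adjusted p = 0.0085, but adjusted p = 0.314 with an estimated correlation). Beside Hbz the embryonic and fetal globin genes Hbe1 (-2.39 ± 0.34) and Hbg1 (-1.36 ± 0.31) fell. In the smooth muscle and mesenchyme list 8 of 24 genes fell and 2 rose (10 and 2 adjusted over the list alone; adjusted p = 0.053). The contractile genes Actg2 (-1.22 ± 0.24) and Tagln (-1.17 ± 0.18) were lower and the mesenchymal regulator gene Tcf21 (0.93 ± 0.14) higher. Of 7 mRNAs with an iron-responsive element 3 rose (3 higher and 1 lower adjusted over the list alone; adjusted p = 0.0462, but adjusted p = 0.214 with an estimated correlation and 0.0615 after quantile normalization). Epas1, the endothelial hypoxia factor gene, rose by 1.33 ± 0.13.

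Several lists had members that moved while the list did not pass camera. In the extracellular matrix list 7 of 48 genes rose and 8 fell (11 and 8 adjusted over the list alone; adjusted p = 0.967), with Fbln5 at 1.23 ± 0.17 against Col18a1 at -2.36 ± 0.29 and Fbn2 at -1.23 ± 0.14. In the branching and morphogen list 5 of 42 rose and 6 fell (6 and 7 adjusted over the list alone; adjusted p = 0.454): the hedgehog target Gli1 fell by 2.16 ± 0.35 and the hedgehog antagonist Hhip rose by 1.39 ± 0.21. The antioxidant list had 7 of 26 higher and 3 lower (8 and 3 adjusted over the list alone; adjusted p = 0.353), with Gsta1 at 1.74 ± 0.28 and Mgst1 at 0.93 ± 0.11. The hypoxia list had 6 of 29 higher and 3 lower (7 and 4 adjusted over the list alone; adjusted p = 0.83), with Pfkfb3 at 1.78 ± 0.31 and Eno1 at -0.91 ± 0.18. The list of endoplasmic reticulum stress had 2 of 30 higher and 8 lower (3 and 9 adjusted over the list alone; adjusted p = 0.187), or 2 higher and 3 lower after quantile normalization, with Psat1 at -0.95 ± 0.17. Heat shock genes had 2 of 16 higher and 3 lower (3 and 4 adjusted over the list alone; adjusted p = 0.354), with Cryab at 1.20 ± 0.25 and Hspd1 at -0.90 ± 0.12. Lipid and sterol synthesis had 5 of 34 higher and 2 lower (6 and 3 adjusted over the list alone; adjusted p = 0.0944), with Lpl at 1.35 ± 0.27 and Elovl6 at -1.04 ± 0.21. Of 16 heart and skeletal muscle genes 0 passed in limma, and over the list alone (adjusted p = 0.968), and the smallest p was that of Pln (0.65 ± 0.33, adjusted p = 0.197). In the list of liver, thymus and neural tissue 4 of 10 fell, 5 adjusted over the list alone (adjusted p = 0.353). Median and mean had opposite signs for the extracellular matrix (0.03 and -0.02), antioxidant (-0.04 and 0.15), hypoxia (-0.10 and 0.12) and liver, thymus and neural (-0.28 and 0.20) lists, for which camera gave down, up, up and down.

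With camera's preset correlation 16 of the 26 lists passed at FD22 against FD19, and 8 passed with an estimated correlation: type II, type I, airway, endothelium, leukocyte, cell cycle, translation initiation and fetal growth. The number of probe sets was 2330 with the arrays numbered 2 and 3 only, a comparison chosen after seeing the data because the arrays numbered 1 stood apart. The counts of rising type II, type I, airway, endothelial and leukocyte genes were then 14, 11, 8, 16 and 18, and that of falling cell cycle genes 41.

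**Figure D1:**
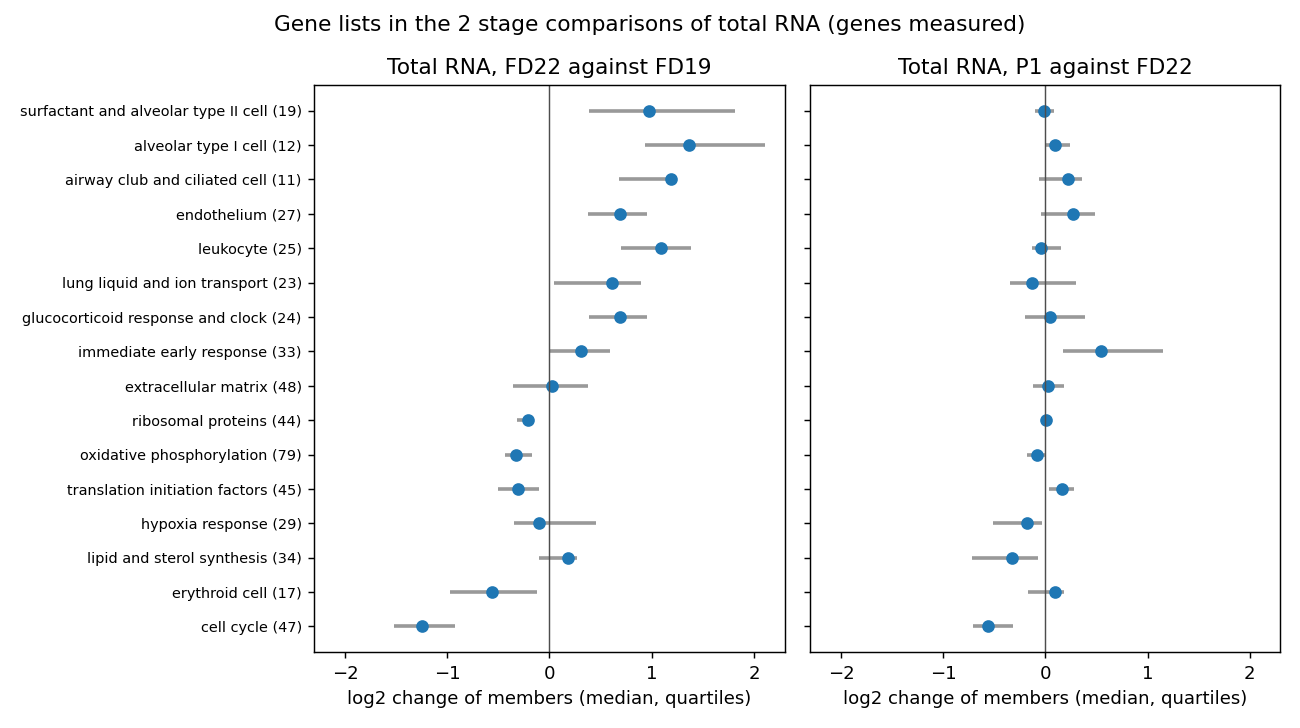
Median log2 change (points) and quartiles (bars) of the members of 16 gene lists in total RNA, FD22 against FD19 (left) and P1 against FD22 (right), with the number of genes measured in brackets. Before birth the epithelial, endothelial and leukocyte lists had medians from 0.69 to 1.36 and the cell cycle list -1.24, and across birth the immediate early list had the highest median shown (0.54) and the cell cycle list the lowest (-0.56).

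The comparison of P1 with FD22 in total RNA asked what changed in the first 5 h after birth. Birth, air breathing and the route of delivery changed together, since the fetuses were delivered by Caesarean section and the newborns were born vaginally. Immediate early genes rose as a list. Some genes of the hypoxia response (5 of 29), of lipid and sterol synthesis (8 of 34) and of the cell cycle (13 of 47) fell, and these lists had adjusted p = 0.409, 0.185 and 0.264 with an estimated correlation. Ier3, an immediate early survival gene, rose by 2.66 ± 0.19 (adjusted p = 2.97e-07), and Ddit4, a gene induced by low oxygen and by glucocorticoids, fell by 1.87 ± 0.20 (adjusted p = 1.81e-05). The surfactant protein genes, of which all but Sftpc had risen before birth, were not called: Sftpa1 stood at 0.08 ± 0.12 (adjusted p = 0.823), Sftpb at 0.21 ± 0.19 (0.633), Sftpc at -0.07 ± 0.21 (0.922) and Sftpd at 0.06 ± 0.19 (0.927). In all, 479 probe sets were higher and 382 lower at P1, 242 of them by more than 2-fold, and with each array centred on its median the split was 637 higher and 260 lower. The 3 arrays of each stage did not overlap for 854 of the 861 and for 20.75% of all probe sets, where chance gives 10%.

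The largest rises across birth were those of Angptl4, a lipase inhibitor (3.24 ± 0.39), Tnfrsf12a, the receptor of the cytokine TWEAK (3.05 ± 0.25), Fam107a (2.87 ± 0.43), the growth factor gene Areg (2.83 ± 0.28), Lrrc32 (2.83 ± 0.30) and the stress transcription factor gene Atf3 (2.77 ± 0.26). The highest adjusted p among them was 0.00069. The signal of Angptl4 went from 21.2 ± 15.5 (SD, n = 3) to 237 ± 116. The deepest falls that passed were those of Veph1 (-2.39 ± 0.63, adjusted p = 0.038), Mesp1 (-1.91 ± 0.44, 0.0184), Ankrd37 (-1.89 ± 0.27, 0.000493), Ddit4, Trpc2 (-1.83 ± 0.29, 0.0013) and Trim45 (-1.80 ± 0.28, 0.00112). The call of Veph1 ended without any lysate of these stages except P1 replicate 1, with adjusted p of 0.12, 0.119 and 0.0628 without FD22 replicates 1, 2 and 3 and 0.154 and 0.0622 without P1 replicates 2 and 3. That of Mesp1 ended without FD22 replicate 1 (0.0918) and without P1 replicates 1 (0.0818), 2 (0.0641) and 3 (0.0609).

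Of 33 immediate early genes 12 rose and 1 fell (17 and 1 adjusted over the list alone; median 0.54, camera adjusted p = 2.22e-14, and 0.00798 with an estimated correlation). Beside Ier3 and Atf3 they included Fosb (2.45 ± 0.46) and Fos (1.82 ± 0.24). In the hypoxia list 5 of 29 genes fell and 0 rose (6 and 1 adjusted over the list alone; median -0.18, adjusted p = 0.00527, but adjusted p = 0.409 with an estimated correlation). They included Ankrd37, Ddit4, the prolyl hydroxylase gene Egln3 (-1.12 ± 0.16) and the collagen hydroxylase gene P4ha1 (-1.12 ± 0.17). Vegfa stood at -0.33 ± 0.18 (adjusted p = 0.367) and passed without FD22 replicate 2 (-0.58, adjusted p = 0.0381). Lipid and sterol synthesis genes fell in 8 of 34 cases (11 lower and 1 higher adjusted over the list alone; median -0.33, adjusted p = 0.000339, but adjusted p = 0.185 with an estimated correlation). Mvd (-1.78 ± 0.33) and Fdft1 (-0.96 ± 0.18), both enzymes on the way to cholesterol, were the lowest. That count was 2 without FD22 replicate 2 and 5 with the arrays numbered 2 and 3 only.

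Cell cycle genes fell further in 13 of 47 cases and rose in 1 (25 and 1 adjusted over the list alone; median -0.56, camera adjusted p = 6.57e-13, but adjusted p = 0.264 with an estimated correlation). Pbk fell by 1.20 ± 0.20, while the cyclin gene Ccnd1, which acts early in the cycle, rose by 1.09 ± 0.18. The count of falling genes was 2 without P1 replicate 1 and 3 with the arrays numbered 2 and 3 only. Endothelial genes rose in 7 of 27 cases and fell in 1 (9 and 3 adjusted over the list alone; median 0.27, adjusted p = 0.000339, but adjusted p = 0.185 with an estimated correlation). Eng, a receptor of the TGF-beta family, rose by 1.06 ± 0.17. That count was 3 without FD22 replicate 1 and 3 with the arrays numbered 2 and 3 only. Translation initiation factors rose in 3 of 45 cases (3 higher and 1 lower adjusted over the list alone; adjusted p = 0.000835, but adjusted p = 0.185 with an estimated correlation), with Eif6 at 0.63 ± 0.11. The antioxidant list passed camera with 0 of 26 genes called in limma and over the list alone (adjusted p = 0.0299, but adjusted p = 0.409 with an estimated correlation and 0.225 after quantile normalization). The iron-responsive element list passed with 1 of 7, and 1 adjusted over the list alone (adjusted p = 0.0128, but adjusted p = 0.185 with an estimated correlation). Only the immediate early list, of the 8 that passed, passed with an estimated correlation. Median and mean had opposite signs for the lung liquid (-0.13 and 0.008), heat shock (-0.08 and 0.14), type I (0.09 and -0.01), smooth muscle (-0.09 and 0.04), erythroid (0.10 and -0.06) and leukocyte (-0.05 and 0.05) lists, and camera gave up for all 6.

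The heat shock genes Hspa1a (1.18 ± 0.17), Hspb8 (1.11 ± 0.22) and Hspb1 (0.90 ± 0.11) rose, 3 of 16 measured and 3 adjusted over the list alone (list adjusted p = 0.18). Among lung liquid genes the water channel gene Aqp3 rose by 1.62 ± 0.23 and the chloride channel gene Cftr fell by 1.04 ± 0.18 (2 higher and 1 lower of 23, and 4 and 2 adjusted over the list alone; list adjusted p = 0.793). Scnn1a stood at 0.62 ± 0.26 (adjusted p = 0.223), Scnn1b at -0.32 ± 0.19 (0.414) and Scnn1g at -0.74 ± 0.21 (0.0524, and 0.0374 after quantile normalization). Meox2, a mesenchymal homeobox gene, fell by 1.06 ± 0.11, the lipoprotein receptor gene Vldlr by 1.19 ± 0.14 and Wnt2 by 1.11 ± 0.20, while Bmp2 rose by 1.06 ± 0.19 and the amino acid transporter gene Slc7a5 by 0.86 ± 0.16. The imprinted gene Mest fell by 0.67 ± 0.13, and Igf2 stood at -0.04 ± 0.17 (adjusted p = 0.944). Ribosomal protein genes in total RNA had a median change of 0.003, with 0 of 44 past the threshold in limma and 0 over the list alone (camera adjusted p = 0.285). Oxidative phosphorylation genes had a median of -0.09 with 0 of 79 past it (adjusted p = 0.259, and 0.00668 after quantile normalization). The number of probe sets called was 467 without FD22 replicate 2, 465 without P1 replicate 1, 447 without P1 replicate 3 and 394 with the arrays numbered 2 and 3 only.

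The same stage comparisons in polysomal RNA asked whether the mRNAs on large polysomes changed with the total pool. From FD19 to FD22 they largely did: of 1122 genes higher in total RNA, 816 were also higher in polysomal RNA (72.7%), of 1199 lower genes 725 were also lower (60.5%), and 0 were called in opposite directions. Independent lists of these sizes would share 113.4 and 114.6 genes. The changes correlated across genes with Pearson r = 0.847, where simulated unchanged groups with the lysates shared gave 0.281 (highest of 100 draws 0.562). Genes are not independent replicates, and part of the excess may come from the shared lysates, although the covariance was 0.2472 against a simulated 0.0184. Across birth 221 of 304 higher genes (72.7%) and 176 of 268 lower genes (65.7%) were shared, against 14.4 and 15.5 for independent lists, with 1 opposite call, r = 0.672 (simulated 0.327, highest 0.524) and a covariance of 0.1011 (simulated 0.0195). In polysomal RNA 1781 probe sets were higher and 1670 lower at FD22 than at FD19 (1996 in all without FD19 replicate 2 and 2290 without FD19 replicate 1). Between FD22 and P1 821 were higher and 986 lower, or 1050 and 747 with each array centred on its median. The total of 1807 was 1152 and 1075 without FD22 replicates 1 and 2 and 1153, 1189 and 1147 without P1 replicates 1, 2 and 3.

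Many ribosomal protein mRNAs on polysomes fell before birth and many rose after it. Between FD19 and FD22 31 of 44 fell (36 adjusted over the list alone; median -0.50, camera adjusted p = 4.61e-15, but adjusted p = 0.127 with an estimated correlation). That count was 18 without FD19 replicate 1. Between FD22 and P1 29 of 44 rose (37 adjusted over the list alone; median 0.49, adjusted p = 1.1e-20, but adjusted p = 0.122 with an estimated correlation), or 18 of 44 after quantile normalization. That count was 8 without P1 replicate 2, whose polysomal ribosomal protein level was the highest of the stage. The 3'/5' signal ratio of beta-actin is a sign of RNA quality. On the polysomal arrays it averaged 1.282 ± 0.187 (SD, n = 3) at FD19, 1.607 ± 0.463 at FD22 and 1.702 ± 0.348 at P1. Within stages the ribosomal protein level was higher where that ratio was higher (r = 0.735, exact permutation test, p = 0.0231, n = 9 arrays), and for the 3'/5' ratio of Gapdh r was 0.688 (p = 0.0972). The other TOP mRNAs moved the same way. Before birth 8 of 13 fell (8 adjusted over the list alone; median -0.51, adjusted p = 3.33e-05, but adjusted p = 0.0991 with an estimated correlation). After it 7 rose (8 higher and 1 lower adjusted over the list alone; median 0.43, adjusted p = 6.43e-06, but adjusted p = 0.122 with an estimated correlation), a count that was 4 without FD22 replicate 2. Translation initiation factor mRNAs rose on polysomes in 15 of 45 cases across birth and fell in 1 (18 and 1 adjusted over the list alone; adjusted p = 2.89e-06, but adjusted p = 0.0788 with an estimated correlation). Their number was 6 without P1 replicate 2 and 5 with the arrays numbered 2 and 3 only. Immediate early mRNAs rose on polysomes in 20 of 33 cases and fell in 2 (21 and 2 adjusted over the list alone; median 0.66, adjusted p = 7.28e-12, and 0.0194 with an estimated correlation). There were 13 without FD22 replicate 2 and 12 with the arrays numbered 2 and 3 only. Extracellular matrix mRNAs, which had not moved as a list in total RNA, rose on polysomes from FD19 to FD22 in 15 of 48 cases and fell in 3 (16 and 4 adjusted over the list alone; median 0.27, adjusted p = 0.000187, but adjusted p = 0.174 with an estimated correlation). Lipid and sterol mRNAs fell on polysomes across birth in 11 of 34 cases (15 lower and 4 higher adjusted over the list alone; median -0.46, adjusted p = 0.000206, but adjusted p = 0.122 with an estimated correlation). Of 16 lists that passed in polysomal RNA before birth, 6 passed with an estimated correlation: type II, type I, airway, endothelium, leukocyte and cell cycle. Across birth 10 passed, and with an estimated correlation only the immediate early list did.

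**Figure D2:**
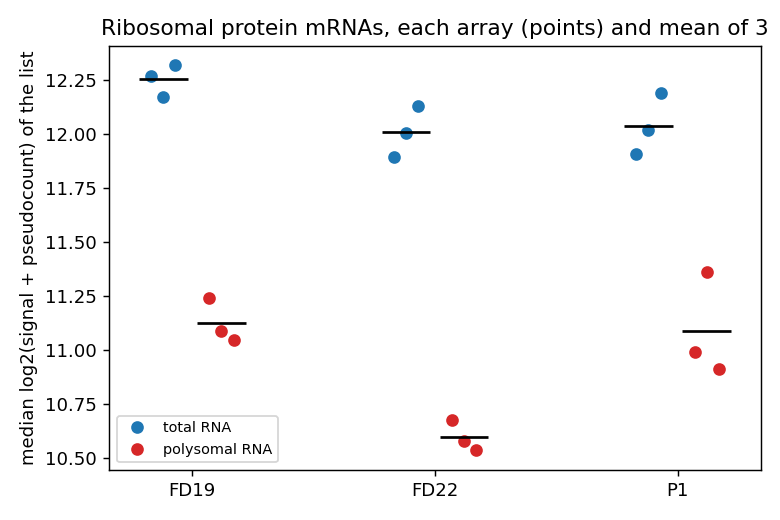
Median log2 signal of the 44 ribosomal protein genes on each array (points), with the mean of 3 arrays (lines), in total RNA (blue) and polysomal RNA (red). The polysomal means were 11.12 at FD19, 10.59 at FD22 and 11.09 at P1, with the P1 arrays spread over 10.91 to 11.36, while the total RNA means were 12.26, 12.01 and 12.04.

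The comparison of polysomal with total RNA asked which mRNAs were over- or under-represented on large polysomes. Because all arrays were scaled alike, a ratio is relative to the average mRNA and not to the amount of RNA on polysomes. Short reading frames hold few ribosomes, and reading frame lengths were not used. A low ratio is therefore not by itself a sign of weak translation. Ribosomal protein mRNAs were the clearest group on the low side, and they were not compared with mRNAs of the same reading frame length. Over the 3 stages 41 of 44 were lower and 2 higher in polysomal RNA (41 and 2 adjusted over the list alone), with a median log2 ratio of -0.99 (camera adjusted p = 3.26e-30, but adjusted p = 0.104 with an estimated correlation). Rpl37a stood at -1.75 ± 0.09 (adjusted p = 4.24e-11, n = 9 lysates), Rps28 at -1.72 ± 0.10, Rps15 at -1.61 ± 0.11 and Rpl41 at -1.61 ± 0.09. The 2 higher genes, named here after their values were seen, were the paralogs Rpl7l1 (0.43) and Rps4y2 (0.85). The other TOP mRNAs were lower in 13 of 13 cases (13 adjusted over the list alone; median -0.59, adjusted p = 1.46e-08, but adjusted p = 0.104 with an estimated correlation). The elongation factor genes Eef1g and Eef2 stood at -1.16 ± 0.06 and -0.77 ± 0.07. Erythroid mRNAs were lower in 14 of 17 cases (14 lower and 1 higher adjusted over the list alone; median -1.04, adjusted p = 2.23e-07, but adjusted p = 0.104 with an estimated correlation). The lowest were the erythroid transcription factor gene Klf1 (-2.02 ± 0.24), the alpha-globin chaperone gene Ahsp (-1.85 ± 0.16), Hbg1 (-1.83 ± 0.18) and Epb42 (-1.75 ± 0.20).

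The genes lowest on polysomes were Myh1 (-3.41 ± 0.15), a myosin heavy chain gene, the selenoprotein gene Selenow (-2.62 ± 0.12), the long noncoding RNA H19 (-2.33 ± 0.14), Rnf151 (-2.29 ± 0.17), the mitochondrially encoded COX2 (-2.27 ± 0.10) and the small nucleolar RNA host gene Snhg11 (-2.26 ± 0.25). The highest were Cryl1 (2.42 ± 0.14), the carbonyl reductase gene Cbr3 (2.12 ± 0.25), the exosome subunit gene Exosc5 (1.93 ± 0.16), Morn1 (1.77 ± 0.23), the cyclophilin gene Ppic (1.54 ± 0.08) and Ndufs4 (1.51 ± 0.18), a subunit of respiratory complex I. The highest adjusted p among these 12 was 6.63e-06. Surfactant mRNAs lay slightly on the high side: Sftpa1 at 0.47 ± 0.07 (adjusted p = 3.73e-05), Sftpd at 0.43 ± 0.11 (0.00429), Sftpb at 0.41 ± 0.11 (0.0046) and Napsa at 0.77 ± 0.18 (0.00213). In all 10 of 19 type II genes were higher and 3 lower (10 and 3 adjusted over the list alone; adjusted p = 0.353, and 0.0286 after quantile normalization). Another probe set of Sftpb was called in the opposite direction, as was another of Gmnn (0.61 ± 0.08) and of Bnip3l (-0.63 ± 0.07). Sftpc was lower (-0.40 ± 0.12, adjusted p = 0.0119) and turned to 0.11 after quantile normalization (0.0703). Igf2 (-0.64 ± 0.10, 3.98e-05), Scnn1b (-0.53 ± 0.11, 0.000661) and Vegfa (-0.46 ± 0.10, 0.00132) were lower, while Scnn1a stood at -0.09 ± 0.15 (0.665) and Scnn1g at 0.02 ± 0.12 (0.889).

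Some families split. Extracellular matrix mRNAs were lower in 19 of 48 cases and higher in 11 (19 and 13 adjusted over the list alone; adjusted p = 0.097). Its lowest members were the collagen genes Col4a2 (-1.29 ± 0.13), Col5a1 (-1.12 ± 0.20), Col4a1 (-0.98 ± 0.07) and Col5a2 (-0.95 ± 0.07). Smooth muscle genes held Myh11 at -1.35 ± 0.11 against Tagln at 1.04 ± 0.10 and Myl9 at 0.96 ± 0.14 (9 of 24 higher and 5 lower, and 10 and 5 adjusted over the list alone; adjusted p = 0.51). Antioxidant genes were higher in 14 of 26 cases and lower in 5 (15 and 5 adjusted over the list alone; adjusted p = 0.105). The glutathione peroxidase genes Gpx4 (-0.92 ± 0.15), Gpx2 (-0.84 ± 0.13) and Gpx1 (-0.82 ± 0.12) were low and Gsta1 (0.93 ± 0.16) high. Oxidative phosphorylation genes were higher in 25 of 79 cases and lower in 29 (25 and 30 adjusted over the list alone; adjusted p = 0.751), from Cox8a (-1.20 ± 0.14) and Uqcrh (-1.13 ± 0.16) to Ndufs4. Translation initiation factors were even at 14 higher and 14 lower of 45 (14 and 14 adjusted over the list alone; adjusted p = 0.842), with Eif3a at -1.18 ± 0.10 and Eif4ebp2 at -1.02 ± 0.10. Immediate early mRNAs held Gadd45g (1.33 ± 0.10) and Gadd45b (1.30 ± 0.12) against Ier3 (-0.86 ± 0.11), with 8 of 33 higher and 9 lower (8 and 9 adjusted over the list alone; adjusted p = 0.751). Endothelial genes were higher in 10 of 27 cases and lower in 2 (10 and 2 adjusted over the list alone; adjusted p = 0.125), with Fabp4 at 1.41 ± 0.19 and Nos3 at -0.93 ± 0.12. Among leukocyte genes 7 of 25 were higher and 4 lower (7 and 3 adjusted over the list alone; adjusted p = 0.571), with RT1-Bb at 1.05 ± 0.10 and Tyrobp at -1.09 ± 0.16. Alas2 (-1.26 ± 0.11), the heme synthesis gene, was the lowest of the iron-responsive mRNAs (3 of 7 lower, and 3 adjusted over the list alone; adjusted p = 0.0995). Median and mean had opposite signs for the initiation factor (0.06 and -0.03), immediate early (-0.12 and 0.001) and branching (-0.04 and 0.06) lists, and camera gave down for the hypoxia, endoplasmic reticulum stress and heart and skeletal muscle lists, whose medians were 0.09, 0.02 and 0.08.

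Over the 3 stages 4085 probe sets were higher and 5972 lower in polysomal RNA, 134 and 670 of them by more than 2-fold, and the split was 4889 and 4233 after quantile normalization and 5121 and 4684 with each array centred. The per-lysate differences had 1 sign in all 9 lysates for 5813 of the 10057 called. At single stages 4525 (2161 higher), 3329 (1465 higher) and 4004 (1760 higher) probe sets were called at FD19, FD22 and P1. The majority turned to the higher side at all 3 stages after scaling anew: the higher and lower calls were 2327 and 1899 at FD19, 1688 and 1409 at FD22 and 1824 and 1596 at P1 after quantile normalization. After centring they were 2463 and 1988, 2121 and 1352, and 2297 and 1699. With the lysate as a block the counts at FD22 and P1 were 5653 and 6058. They were 2554, 1722 and 1700 without FD19 replicates 1, 2 and 3, 1957 and 1268 without FD22 replicates 2 and 3, and 2309, 1977 and 1866 without P1 replicates 1, 2 and 3. Ribosomal protein mRNAs were lower in 39, 40 and 38 of 44 cases at the 3 stages (40, 41 and 41 adjusted over the list alone; medians -0.99, -1.26 and -0.78), with adjusted p = 0.121, 0.0296 and 0.165 with an estimated correlation. Of the lists that passed at a single stage, only this one and the other TOP mRNAs at FD22 (median -0.71, 0.0296) passed with an estimated correlation, and 0 lists did so in the ratio changes between stages. Extracellular matrix mRNAs passed camera at FD19 alone (17 of 48 lower and 5 higher, and 22 and 7 adjusted over the list alone; median -0.32, adjusted p = 1.34e-05, but adjusted p = 0.223 with an estimated correlation). So did the fetal growth list (5 of 21 lower, and 8 adjusted over the list alone; adjusted p = 0.00372, but adjusted p = 0.132 with an estimated correlation). With the lysate as a block the endothelium list also passed at FD19 (median 0.15, adjusted p = 0.0724, and 0.0373 with the block) and the iron-responsive element list at P1 (median -0.19, adjusted p = 0.0565, and 0.0472 with the block).

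**Figure D3:**
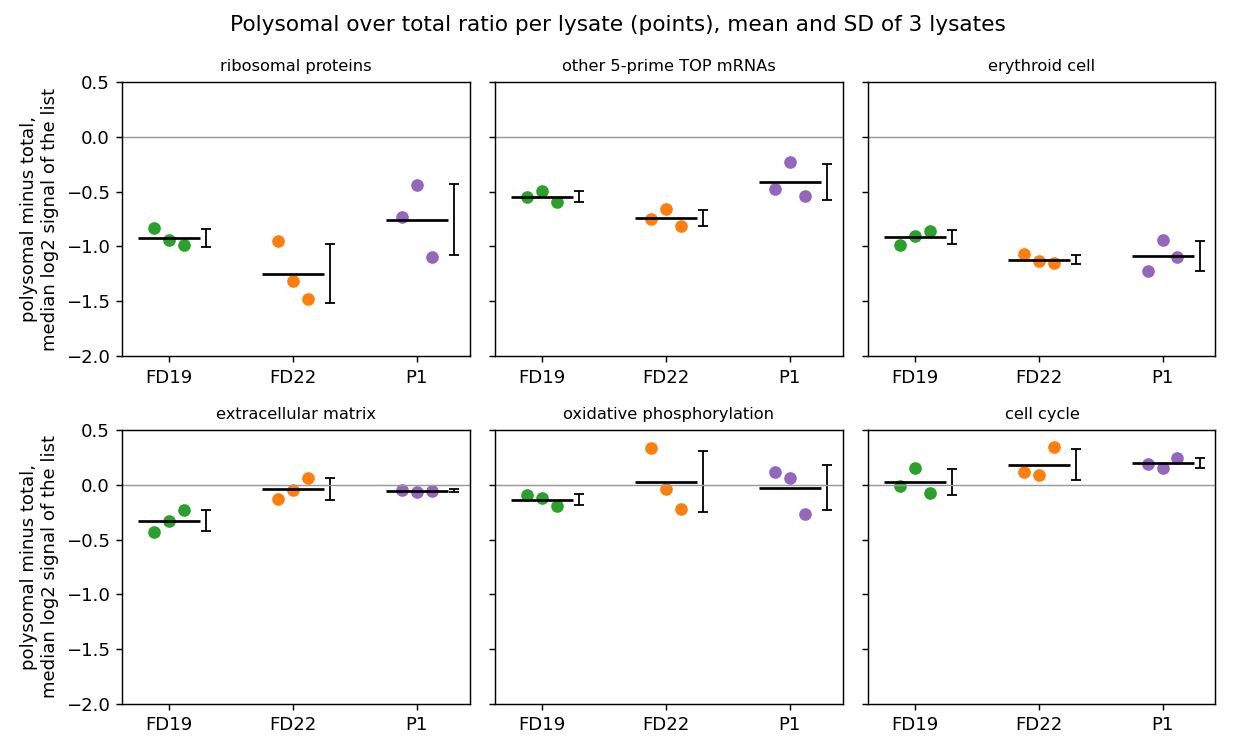
Polysomal minus total log2 signal per lysate (points), as the median over each of 6 gene lists, with the mean and SD of the 3 lysates of a stage (lines and bars). The ribosomal protein ratio averaged -0.92 at FD19, -1.25 at FD22 and -0.75 at P1, a P1 against FD19 change that reversed sign after quantile normalization, and the erythroid ratio lay between -0.92 and -1.12 at all stages, while the extracellular matrix ratio went from -0.33 at FD19 to -0.04 at FD22.

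The change of the polysomal over total ratio between stages asked which mRNAs moved onto or off large polysomes. Such a change has a median SE of 0.298 against 0.21 for a stage comparison, and on simulated data with P1 and FD22 compared 29.9% of 2-fold changes were recovered. Between FD19 and FD22 0 of 21675 probe sets passed in limma, with 781 at an unadjusted p under 0.05. The smallest p-values were those of the ribosomal protein gene Rplp0 (-0.75 ± 0.15), Sftpa1 (-0.83 ± 0.17), the surfactant protease gene Ctsh (-0.90 ± 0.19) and the microfibril gene Fbn2 (0.91 ± 0.20), each with adjusted p = 0.987. Sftpb stood at -0.79 ± 0.26 and Sftpd at -0.57 ± 0.27 (both adjusted p = 0.999).

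Some gene lists passed camera with its preset correlation in these ratio changes, where few single genes passed. With an estimated correlation 0 of these lists passed. From FD19 to FD22 the ratio of extracellular matrix mRNAs went up (median 0.28, camera adjusted p = 2.99e-12, but adjusted p = 0.114 with an estimated correlation), with 0 of 48 called over all genes in limma and 3 adjusted over the list alone. The ribosomal protein ratio went down (median -0.25, adjusted p = 2.47e-13, but adjusted p = 0.34 with an estimated correlation), with 0 of 44 called and 1 adjusted over the list alone, and with a median of -0.49 after quantile normalization. From FD22 to P1 the ribosomal protein ratio went up (median 0.48, adjusted p = 7e-29, but adjusted p = 0.227 with an estimated correlation), with 0 of 44 called and 26 adjusted over the list alone. Within stages the ribosomal protein ratio was higher in lysates whose beta-actin 3'/5' ratio was higher in polysomal than in total RNA (r = 0.834, exact permutation test, p = 0.0139, n = 9 lysates), and for Gapdh r was 0.858 (p = 0.0556). The ratio of oxidative phosphorylation mRNAs went with it too (r = 0.956, p = 0.00463), and those of lipid synthesis (r = -0.899, p = 0.0231) and type II cell mRNAs (r = -0.591, p = 0.00463) against it. With the polysomal level above, these were 5 of 52 correlations with beta-actin that had an unadjusted p under 0.05, computed after the results were seen, and the smallest possible p was 0.00463. For beta-actin and Gapdh together 10 of 104 had such a p. The other TOP mRNAs did the same (median 0.31, adjusted p = 3.69e-06, but adjusted p = 0.227 with an estimated correlation), with 0 of 13 called and 4 adjusted over the list alone. Per lysate the ribosomal protein ratio differed between FD22 and P1 by 0.495 (exact permutation test, p = 0.2) and the polysomal level by 0.494 (exact permutation test, p = 0.1), where 3 lysates against 3 cannot go below 0.1, so that neither test could reach 0.05. The endothelium ratio from FD19 to FD22 had a median of -0.13 (adjusted p = 0.0561, and 0.0315 with the lysate as a block).

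Most of the single mRNAs that passed were lower in polysome share at P1. From FD22 to P1 they were Arpc5l (-1.33 ± 0.19, adjusted p = 0.0182), an actin nucleation subunit, the phosphatase inhibitor gene Ppp1r2 (-1.63 ± 0.26, 0.0416) and Ccnyl1 (-1.32 ± 0.21, 0.0416), 3 probe sets in all, against 943 at an unadjusted p under 0.05. With the lysate as a block 17 passed, and Insig1, a brake on sterol synthesis, was among them (-1.15 ± 0.23, adjusted p = 0.227, and 0.0088 with the block). From FD19 to P1 1 probe set was higher and 24 lower: Hspd1, a mitochondrial chaperone gene, rose by 0.87 ± 0.17 (0.0459, and 0.1 after quantile normalization). Ppp1r2 (-1.70 ± 0.26), the polyamine synthesis gene Amd1 (-1.54 ± 0.24), the mitochondrial kinase gene Pink1 (-1.48 ± 0.24), Ier3 (-1.40 ± 0.26), Alas2 (-1.40 ± 0.26), Tmem179b (-1.30 ± 0.24) and Insig1 (-1.29 ± 0.23) fell, with adjusted p of 0.0269 or 0.0459. With the block 226 passed, 43 higher and 183 lower. They included Sftpa1 (-0.73 ± 0.17, adjusted p = 0.127, and 0.0247 with the block), Ctsh (-0.76 ± 0.19, 0.149 and 0.0228) and Fbn2 (0.92 ± 0.20, 0.0741 and 0.0298). The fibronectin gene Fn1 (0.75 ± 0.17, 0.0978 and 0.0204), the chaperone gene Hspa5 (1.01 ± 0.27, 0.165 and 0.0397) and Gpc3 (0.80 ± 0.20, 0.149 and 0.0401) were also among them. The counts without the block rested on all lysates. From FD22 to P1 0 passed in limma without FD22 replicates 1 or 2 or P1 replicates 2 or 3, 2 without P1 replicate 1 and 20 without FD22 replicate 3. From FD19 to P1 1 passed without P1 replicate 1 and 0 without any other lysate of these stages. The sodium channel and growth genes showed no call in any of these changes, with Scnn1a at -0.27 ± 0.37 (adjusted p = 0.893), Scnn1b at -0.19 ± 0.27 (0.892), Scnn1g at 0.44 ± 0.29 (0.695), Vegfa at -0.04 ± 0.25 (0.983) and Igf2 at -0.08 ± 0.24 (0.962) from FD19 to P1.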

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

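The tests of permutation, RNA quality, short reading frames, membrane-bound polysomes (with its interval between lysates) and label splits were chosen after the results were seen, and those of brightness, single lysates and arrays numbered 1 were written before their outcome was known. The changes of the polysomal over total ratio between stages are set apart here because each compares differences between lysates. A stage difference in polysome share was tested for the first of the 3 patterns weighed and short reading frames for the second, and no biological explanation was tested for the third.

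From FD19 to FD22 the median log2 ratio changes of the lists that passed camera were -0.253 for ribosomal proteins, -0.148 for other 5-prime TOP mRNAs, -0.185 for type II cells and -0.227 for type I cells. On the high side they were 0.205 for the cell cycle, 0.131 for oxidative phosphorylation, 0.278 for the extracellular matrix, 0.07 for endoplasmic reticulum stress and 0.097 for the fetal growth list. The adjusted p with an estimated correlation was 0.114 for the extracellular matrix, 0.34 for ribosomal proteins, other TOP mRNAs, type II cells, endoplasmic reticulum stress and fetal growth, 0.479 for type I cells and 0.73 for the cell cycle and oxidative phosphorylation. After quantile normalization the calls of type II cells (0.106), type I cells (0.687), oxidative phosphorylation (0.121), endoplasmic reticulum stress (0.148) and fetal growth (0.272) were lost.

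From FD22 to P1 3 probe sets were called, Ppp1r2 (-1.626), Arpc5l (-1.33) and Ccnyl1 (-1.32), and the medians of the ribosomal protein and other TOP lists were 0.475 and 0.311 (adjusted p = 0.227 with an estimated correlation for each). From FD19 to P1 25 were called, among them Hspd1 (0.872), Ppp1r2 (-1.701), Amd1 (-1.539), Pink1 (-1.48), Ier3 (-1.4), Alas2 (-1.397), Tmem179b (-1.304) and Insig1 (-1.292). The medians of the lists that passed were 0.21 for the cell cycle, 0.194 for ribosomal proteins, 0.336 for the extracellular matrix, 0.218 for endoplasmic reticulum stress and 0.247 for fetal growth. With an estimated correlation their adjusted p was 0.936, 0.936, 0.383, 0.435 and 0.465, and after quantile normalization the ribosomal protein median turned to -0.187 (adjusted p = 0.000178). Endoplasmic reticulum stress (0.11) and fetal growth (0.514) then lost their call, while the cell cycle (0.000524) and the extracellular matrix (2.33e-05) kept it.

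The rise of ribosomal protein mRNAs in polysomal RNA between FD22 and P1 had a median of 0.494, at the percentile 100 of random lists of the same brightness, whose central range was 0.063 to 0.223. The lowest median with 1 lysate left out was 0.339, without P1 replicate 2 (random lists up to 0.169), and the median was 0.586 with the arrays numbered 2 and 3 only. Brightness, 1 lysate or the arrays numbered 1 alone therefore did not give the whole shift of the median. Random lists of the same brightness rose by a median of 0.153, and the called members fell to 8 of 44 without P1 replicate 2. The random lists were drawn gene by gene and do not carry the correlation between ribosomal protein genes, so their percentile does not test the stage effect. With the beta-actin 3'/5' ratio of the polysomal arrays as a covariate the rise was 0.458 (95% interval 0.211 to 0.704), and with that of Gapdh 0.493 (0.233 to 0.754). Neither ratio therefore accounted for the rise, and their means differed little between FD22 and P1 (1.607 and 1.702, 1.355 and 1.352). The 3'/5' ratio of Hexokinase averaged 2.399 ± 0.381 (SD, n = 3) at FD22 and 1.954 ± 0.416 at P1. It was not used as a covariate, so RNA quality as a whole stays open. Whether the share of ribosomal protein mRNAs on large polysomes changed between the stages stays open. The exact permutation p was 0.2 for the ratio and 0.1 for the polysomal level, where 0.1 is the smallest possible, so the test could not decide. In the linear model of stage the ratio rose by 0.495 (95% interval -0.002 to 0.992). With the beta-actin 3'/5' ratio as a covariate the rise was 0.435 (0.117 to 0.754), which leaves out 0. This covariate was added after the results were seen and went with this same ratio within stages, so its interval does not decide the question. The ratio of the other TOP mRNAs rose by 0.328 (0.111 to 0.544) without the covariate.

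Erythroid mRNAs were lower in polysomal than in total RNA, with a median of -1.035 at the percentile 0 of lists of the same brightness (-0.278 to 0.212), so brightness was not the cause. Globins have short reading frames that hold few ribosomes, and 4 of 4 globin genes were lower (2 of 4 after quantile normalization; median -1.192). Of the 13 other members 10 were lower and 0 higher, with a median of -1.035 (95% interval over resampled members -1.358 to -0.686, percentile 0), and the 5 coding for large proteins had a median of -0.686, at the percentile 0.29 of lists of the same brightness (-0.492 to 0.412), which argues against short reading frames of the globins as the whole cause. Only 5 of the 13 were brighter than the median gene, with a median of -0.974, at the percentile 0.02 of lists of the same brightness (-0.306 to 0.493). Their interval over resampled members was -1.845 to 0.262, a condition added after the 13 together had excluded the explanation. With 5 members that interval only spans the lowest and the highest value, so it could not decide. The 4 globins differed: Hbg1 stood at -1.825 and Hbe1 at -1.632, but the bright Hbb at -0.398, or 0.07 after quantile normalization (limma adjusted p = 0.182). Hbz (-0.752) was dim, with a mean log2 signal of 4.11. This spread was not compared with reading frame lengths, which were not used, so the explanation stays open for the globins themselves. Of the large proteins Epb42 (-1.75) and Ank1 (-0.69) were dim, with mean log2 signals of 5.71 and 6.19, Slc4a1 (-0.97) passed, and Tfrc (-0.22) and Sptb (0.089, adjusted p = 0.807) did not.

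The extracellular matrix ratio rose from FD19 to FD22 by a median of 0.278, at the percentile 100 of lists of the same brightness (-0.058 to 0.104), and the lowest median with 1 lysate left out was 0.215 (random lists up to 0.093). Neither brightness nor 1 lysate alone gave the rise of the median, although the random lists do not carry the correlation between the members. A different recovery of membrane-bound polysomes between the stages stays open. The endothelium list, also rich in membrane and secreted proteins, moved by a median of -0.134, but its ratio per lysate changed by -0.055 with a 95% interval of -0.41 to 0.3 (t interval, 3 lysates per stage), too wide to exclude it.

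Exchanging group labels tested the counts of called probe sets, and with 10 splits the share cannot be under 0.05. For total RNA the real counts were 3520 from FD19 to FD22 and 861 from FD22 to P1, each reached in 1 of 10 splits, with 1 and 2 as the highest other counts. For polysomal RNA they were 3451 and 1807, each in 1 of 10, with 0 and 1. For polysomal against total RNA they were 4525 at FD19, 3329 at FD22 and 4004 at P1, each in 1 of 10, with 0, 159 and 1 as the highest others. Among the 4 splits that part all pairs, the real one included, the highest other count was 0 at each stage. The mean ratio reached 10057 in 1 of 100 splits, with 5392 as the highest other. Among 100 splits that part all pairs, the real one included, the highest other was 6256. The ratio changes gave 0 from FD19 to FD22 (10 of 10 splits, highest other 0), 3 from FD22 to P1 (1 of 10, highest other 1) and 25 from FD19 to P1 (1 of 10, highest other 0). With the lysate as a block they gave 0 (10 of 10, highest other 1), 17 (1 of 10, highest other 2) and 226 (1 of 10, highest other 0).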

How the results depend on the processing

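The number of arrays, 3 per group, limits the precision, and why the counts and calls in this section moved between settings was not tested. With the arrays numbered 2 and 3 only, chosen after seeing the data, the counts were 2330 and 394 for total RNA before and across birth, 2076 and 812 for polysomal RNA, and 0 for the ratio changes from FD22 to P1 and from FD19 to P1. With only the arrays compared they were 352 for total and 476 for polysomal RNA across birth, 1213 for polysomal against total RNA at FD22, and 0 and 64 for the ratio changes to P1 from FD22 and from FD19. With 1 probe set per gene, which tests fewer probe sets, the polysomal against total counts were 5536 for the mean, 2763 at FD19, 2087 at FD22 and 2520 at P1. For the ratio changes from FD22 to P1 and from FD19 to P1 the counts were 1 and 7 without a filter and 0 and 0 without a variance trend. From FD19 to P1 there were 41 with the filter at the 60th percentile and 7 with median centring, and from FD19 to FD22 there were 4 after quantile normalization. Sftpc in polysomal against total RNA turned from -0.397 to 0.109 after quantile normalization, and the ribosomal protein list in the ratio change from FD19 to P1 reversed (adjusted p = 0.000178).

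With the lysate as a block the counts were 5653 at FD22 and 6058 at P1 for polysomal against total RNA, and 17 and 226 for the ratio changes from FD22 and from FD19 to P1. With the block and quantile normalization, chosen after seeing the data, they were 5076 at FD22 and 12 and 162 for these ratio changes, and Sftpc stood at 0.109. Beyond the calls given with the results, the lysate block changed no call of a list or of a gene named for the same comparison by the rule. Genes named elsewhere in the text that passed only with it were Pla2g1b (adjusted p = 0.0259), Atp6v1c2 (0.0377), Col2a1 (0.0247) and Oip5-as1 (0.0247) from FD19 to P1, and Tmem179b (0.0495) and Amd1 (0.0495) from FD22 to P1. For polysomal RNA at FD22 against FD19, where equal numbers deviated together, the number as a block gave 4577 probe sets and changed no call of a list, and 6 of 6 arrays correlated best with their own number. In the other stage comparisons fewer than 3 of 3 equal numbers correlated above 0.1: 2 in total RNA before birth (-0.031 to 0.371, 4 of 6 arrays best with their own number), 1 in total RNA across birth (0.092 to 0.42, 2 of 6) and 2 in polysomal RNA across birth (0.094 to 0.388, 4 of 6). There the number block served only as a check. As an additive block over all 18 arrays, chosen after seeing the data, it gave 1457 for total and 2731 for polysomal RNA across birth, 5034 for polysomal against total RNA at FD22, and 8 and 139 for the ratio changes to P1. As a block within 1 kind of RNA it moved Scnn1a (adjusted p = 0.0273) and Scnn1g (0.0149) across birth past the threshold. The calls of Mesp1 (0.0752), Eif2s2 (0.0942), Hhip (0.0745) and Spry1 (0.0548) across birth and of Cox8b (0.0555) and Gap43 (0.0936) before it were lost.

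With 1 lysate left out the counts ran from 2359 to 3149 for total RNA before birth and from 447 to 721 across birth, and from 1996 to 3341 and from 1075 to 1887 for polysomal RNA. For polysomal against total RNA they ran from 8353 to 9781 for the mean, from 1700 to 2554 at FD19, from 1268 to 2590 at FD22 and from 1866 to 2309 at P1. For the ratio changes, fitted without the block, they were 0 throughout from FD19 to FD22, 0 to 20 from FD22 to P1 and 0 to 1 from FD19 to P1.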

Other observations

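Long noncoding RNAs, which have no reading frame for many ribosomes, were low in polysomal RNA beyond H19 and Snhg11. Of 109 measured, 71 were lower and 0 higher over the 3 stages (39 lower after quantile normalization), with a median log2 ratio of -0.527, against 0.008 for 11419 protein-coding genes, of which 21.7% were lower. The hypothesis that RNAs without a reading frame are lower was written before testing the other 107, and their median of -0.521 lay at the percentile 0 of protein-coding lists of the same brightness (-0.211 to -0.015), so the hypothesis held. Gas5 (-1.949), itself a host of small nucleolar RNAs and of a TOP motif, Snhg4 (-1.146), Oip5-as1 (-1.071) and Pvt1 (-0.925) were among them. Tug1 (0.104, limma adjusted p = 0.354) and Meg3 (-0.367, 0.309) did not pass.

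Selenow (-2.62) was among the lowest mRNAs on polysomes, and of 5 other selenoprotein genes seen before this test Gpx1 (-0.82), Gpx2 (-0.84) and Gpx4 (-0.92) were low, Txnrd1 (0.47) was higher and Gpx3 stood at -0.04. Selenoproteins read a stop codon as selenocysteine, and the hypothesis that their mRNAs are lower as a class was tested on 13 further genes. Their median was -0.058, at the percentile 18.69 of lists of the same brightness (-0.204 to 0.329), with 4 higher and 3 lower, so the hypothesis failed. Selenos (1.01) and Selenok (0.48) were higher, while Selenoh (-0.67) and Selenom (-0.57) were lower. The mitochondrially encoded mRNAs COX1 (-1.064) and COX2 (-2.271) were lower, and the array was not searched for others. Mitochondrial mRNAs are translated inside the organelle on its own ribosomes.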
